A study of Schizosaccharomyces pombe with 39 samples.

How the data were processed

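Chromatin immunoprecipitation on tiling arrays (ChIP-chip) was read out for 39 samples of Schizosaccharomyces pombe. Per the labels, cells grew at 33 °C and were held at 18 °C for 2 h before fixation with 3% formaldehyde for 35 min. Chromatin was sheared to an average of 500 bp. ChIP DNA (Cy5) and input DNA (Cy3) were each amplified after linker ligation and hybridized together. Per the file headers, the deposited scanner files came from Agilent Feature Extraction and hold spot intensity in arbitrary units. They give mean spot brightness, local background and processed signals after spatial detrending, background subtraction from negative controls and dye normalization, each array on its own. The authors also deposited a table of log2 ChIP/input ratios for all samples, whose normalization is not given in the sources used here. Its values correlated with the scanner log2 ratio at 0.694 to 0.990 over probes, and at a median of 0.997 over arrays within bins of intensity, so it resembles the scanner ratio with an intensity trend removed. Of its columns 38 of 39 columns correlated best with their own array.

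The file headers place the probes on an older genome build than the reference used here (ASM294v3), so the design positions were not used. The 60-base probe sequences were matched exactly to the reference on both strands: 39691 of 40579 probes matched once, 846 more than once and 42 not at all, with a median spacing of 298 bp. Positions differed from those of the design most often by -900 bp on chromosomes 1 and 3 and by -1800 bp on chromosome 2, and 9 probes lay on another chromosome. Probes with a single match were used everywhere except at native centromeres, where all probes were used. Each native centromere was set as the largest cluster on its chromosome of probes with at least 4 matches, joined over up to 20 kb. Its core is the widest gap between such probes.

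The main value is the log2 ratio of the processed ChIP signal to the processed input signal minus the array's median, with probes that the image software marked as outliers left out (0 to 2728 per array). Signal over local background was 6.64 to 399 for ChIP and 71.4 to 312 for input. A domain is a stretch in which the running median over 2 kb is at least 1, joined over gaps of up to 5 kb and at least 3 kb long. The ectopic centromere of a strain (its Cnp1 block) is the longest Cnp1 domain outside the native centromeres on the chromosome that lost its centromere, and its core is the part at or above 3, a threshold chosen after the data were seen. Regions were summarised by the mean and SD over probes and placed among 10000 random runs of as many neighbouring probes on the arms of the same chromosome, without the outermost 20 kb. Genes were measured by the mean over at least 3 probes in the gene body (7609 genes), and subtelomeres are the outermost 100 kb of chromosomes 1 and 2.

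Each protein and strain had 1 array, so contrasts of 2 arrays are values without a test. For Pht1 the carriers of each ectopic centromere were compared with the other arrays by an exact one-sided permutation of the carrier labels over the 7 arrays; a strain counts as a carrier where its own Cnp1 block covers at least 0.5 of the locus. Named genes were fixed by rule, among genes with at least 3 probes all on the same side of 0. They are up to 10 protein-coding genes with the highest Cnp1 in each block, up to 10 genes higher and 10 lower by at least 1 in each contrast, and up to 10 genes of each block with the lowest Pht1 relative to the arrays of non-carriers. The gene at each edge of a block was named without that filter, and each fixed list gave up to 4 examples. The fixed gene lists were native centromere genes and tRNAs (0 of 144 measured), subtelomeric genes (55 of 122) and the mating type locus (0 of 4, of which mat2-Pi and mat2-Pc carry no such name in the annotation used). The others were facultative heterochromatin islands (7 of 8), ribosomal protein genes (35 of 130), glycolysis and housekeeping genes (11 of 12), stress response genes (8 of 9) and histone genes (7 of 9). List medians of a contrast were placed among 10000 random gene lists matched on 10 equal bins of the second array's value.

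The domain rule, gene differences, percentiles and permutation test were tested on simulated data. Added blocks of 60 kb were recovered in 20 of 20 simulations at heights of 1.5, 2 and 4 and in 0 of 20 at 0.5, with a median error of the worse edge of 737 bp at a height of 1.5. Of 200 genes shifted by 1.5 all 200 passed a difference of 1, and 0 did when shifted by 0.5. Without signal the permutation test gave a p of 0.05 or less in 46 of 1000 simulations, and with carriers lowered by 1 in 100 of 100. These simulations used independent values for each array and block, unlike the overlapping blocks of cd389 and cd389-r1. The simulated lowering was also larger than the observed -0.30, so the power for the real blocks is not known from them.

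Alternatives covered background correction (limma normexp with an offset of 50), loess within arrays (limma), the authors' log2 table, a filter on dim probes, centring, domain threshold, window and gap, the median over probes, narrower blocks, scaling to native centromeres or repeats, and other comparators for Pht1. A common input, narrower cores, further comparators and a baseline from the arms of chromosome 3 for Pht1 were added after the data were seen. Sequence similarity between probes was searched with blastn 2.17.0, keeping hits of at least 80% identity over at least 50 bases. Work was done in python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and in R 4.3.3 with limma 3.58.1.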

Results

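The series mapped centromere proteins and heterochromatin marks across the fission yeast genome in strains that had lost a native centromere and carried a centromere at a new place. Its title names a shortage of histone H2A.Z as what stabilizes such ectopic centromeres, and its design compares the survivors of centromere deletion with their derivatives. The 39 two-colour tiling arrays covered 9 proteins or marks in 15 strains: Cnp1, the centromeric histone CENP-A (11 arrays), H3K9me2 (7), Pht1, which is H2A.Z (7), the HP1 protein Swi6 (4), and the kinetochore or loading proteins Cnp3, Cnp20, Mis6, Mis12 and Scm3 (2 each). Besides wild-type and an msc1 deletion (Dmsc1), the strains were cd39 and cd60 without centromere 1, cd163 and cd166 without centromere 2, and cd385, cd389 and cd386-r2 without centromere 3. The rest were derivatives of cd385 and cd389: an r1 line of each, and lines with an integrated vector or an integrated dh2.1 fragment. Every combination of protein and strain was measured on 1 array, so there are no replicates; each SD below is over probes unless it is said to be over strains or arrays, and a single array limits how precisely any value is known.

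The input signal carried the deletions that the labels name. Over the 8 single-match probes of centromere 1 the input was -5.12 on the 2 arrays of strains labelled as lacking it and -1.55 on the other 37 (log2, relative to the array's median). Centromere 2 gave -8.23 on 2 arrays against -2.08 on 37, centromere 3 gave -9.29 on 33 arrays against -1.28 on 6, and msc1 gave -9.23 on the Dmsc1 array against 0.04 on 38. ChIP signal lay 6.64 times above the local background on the dimmest array (Cnp1 in cd389), with a median over arrays of 119.6 times, and 98.4% to 99.96% of probes were well above background. All positions refer to the ASM294v3 assembly, on which 39691 of 40579 probes matched at a single place.

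Cnp1 marked 1 long block of chromatin outside the native centromeres on the chromosome that had lost its centromere, near a chromosome end in 3 of the 4 survivors and well inside the right arm of chromosome 3 in cd385. In cd163 the block ran from 29544 to 90492 on chromosome 2 (60.9 kb, mean log2 ratio 4.19 ± 2.59, 188 probes). Its highest genes were the hexose transporter gene ght7 (8.58), the transcription factor gene SPBC1348.12 (7.52), the urea transporter gene SPBPB8B6.02C (7.30), the acetamidase gene fah1 (4.76) and the transcription factor gene grt1 (4.48), and it also held the methyltransferase gene cmt2 (3.46) and the enolase gene eno102 (3.38). In cd166 the block lay at the opposite end of chromosome 2, from 4419159 to 4493305 (74.1 kb, 4.04 ± 2.47), over the phosphatase gene SPBPB2B2.06C (7.48), the amino-acid permease gene nrg1 (7.20), fub2 (7.07), the sterol deacetylase gene say1 (6.20) and the galactose pathway genes gal1 (5.12), gal7 (3.83) and gal10 (3.71).

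The cd385 block covered 1891658 to 1997348 on chromosome 3 (106 kb, 2.62 ± 2.37, 351 probes), with a core above a ratio of 3 from 1912837 to 1949784. Its highest values were at the transporter gene SPCC74.04 (9.01), ssp2, the catalytic subunit of AMP-activated kinase (5.80), the polyadenylation factor gene ppn1 (5.10), mug24 (4.91), sly1 (4.63) and the sensor kinase gene mak3 (4.44). It faded to 1.55 at SPCC737.04 and 0.81 at the nucleoporin gene nup186 at its edges. In cd389 the block began at the first single-match probe of the left end of chromosome 3 and ran from 24619 to 151076 (126 kb, 2.72 ± 2.71, 390 probes), so its left limit is that of the array. Its core, from 24619 to 78156, held SPCC1884.01 (9.62), the glyoxylase gene hsp3101 (7.83), the nickel transporter gene nic1 (7.66), SPCC757.02C (7.42), the peptidase gene SPCC757.05C (5.22), the transcription factor gene SPCC757.04 (4.96) and the catalase gene ctt1 (3.84). The 5 blocks, that of the derivative cd389-r1 included, wholly contained 17, 20, 34, 53 and 43 protein-coding genes (cd163, cd166, cd385, cd389, cd389-r1), of which 11, 17, 32, 43 and 35 had 3 or more probes and showed median Cnp1 values of 4.16, 3.71, 1.77, 1.91 and 1.57. Among 10000 random runs of as many neighbouring probes on the same chromosome's arms, the blocks of cd163, cd166, cd385 and cd389 stood at percentiles of 99.99, 100, 99.61 and 99.99. Each block was chosen for high Cnp1 on that same array, so these percentiles restate the choice and are not a test of it. Block length depended on the rule, since stretches separated by up to 5 kb were joined. With gaps of up to 1 kb the lengths of the 5 blocks were 24.9, 45.3, 62.4, 51.4 and 32.7 kb. At a threshold of 1.5 those of cd389 and cd389-r1 were 66.7 and 64.3 kb. Part of each ratio over a core came from the input, which on the Cnp1 array read -1.16 over the cd385 core and -0.74 over the cd389 core, against -0.05 and -0.21 on Pht1 arrays of strains with no centromere there. In cd385 a longer Cnp1 domain, of 168 kb at a mean of 1.78, lay beside native centromere 1.

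At the native centromeres Cnp1 averaged 5.58 ± 0.99 over strains at centromere 1, 5.46 ± 0.89 at centromere 2 and 4.49 ± 0.05 at centromere 3, each over the strains that keep it. Only cd163 and cd166 keep centromere 3, so its small SD rests on these strains alone and says little about spread. The core of centromere 1 read 7.23 in cd163, 7.84 in cd385 and 8.81 in cd389. In cd163 the deleted core of centromere 2 read 0.99. Over centromere 3 the value was 2.95 in the authors' deposited log2 table and 6.95 with a common input, while centromeres 1 and 2 kept theirs within 1 SD over strains under every setting tried. No gene inside the native centromeres had 3 single-match probes, so the 144 annotated centromere genes and tRNAs were not measured as genes.

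The inner kinetochore proteins occupied the same places as Cnp1, each in its own survivor. In cd385 the mean over the core of the ectopic centromere was 2.56 for Cnp3 (CENP-C), 2.96 for Cnp20 (CENP-T), 1.68 for Mis6 (CENP-I) and 1.48 for the kinetochore protein Mis12. In cd389 these values were 1.75, 2.20, 2.48 and 1.76, and Scm3, the chaperone that brings Cnp1 to centromeres, read 1.02. Over the entire Cnp1 block the means were lower, from 0.56 ± 1.28 (Mis12) to 1.23 ± 2.00 (Cnp20) in cd385 and from 0.35 ± 1.34 (Scm3) to 1.14 ± 2.16 (Cnp20) in cd389. The longest domain of each protein overlapping the block spanned 20.7 to 33.5 kb in cd385 and 13.2 to 49.2 kb in cd389. The native cores of centromeres 1 and 2 on the same arrays read 6.68 and 7.02 for Cnp3 in cd385, 5.76 and 6.45 for Cnp3 in cd389, 3.89 and 4.11 for Mis6 in cd385, and 4.40 and 4.86 for Scm3 in cd389. At the other survivor's locus Cnp3 read -0.17 in cd385 and -0.18 in cd389. The blocks stood at percentiles of 98.0 to 99.7 among random runs for the 4 kinetochore proteins in cd385 and of 99.98 to 100 for the 5 proteins in cd389. Random runs could overlap the block itself, more so in cd385, whose block lies inside the arm. The SD of random runs for Cnp3 was 0.22 in cd385 and 0.07 in cd389, so these percentiles do not compare the 2 survivors. On the Cnp20 array of cd389 418 domains were called across the genome, the longest of 57.6 kb, so its 49.2 kb span is less specific than the others. These means depended on where the block was drawn and on the input: with a common input over all arrays Mis6 and Mis12 over the cd385 block read 0.16 and 0.22.

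**Figure D1:**
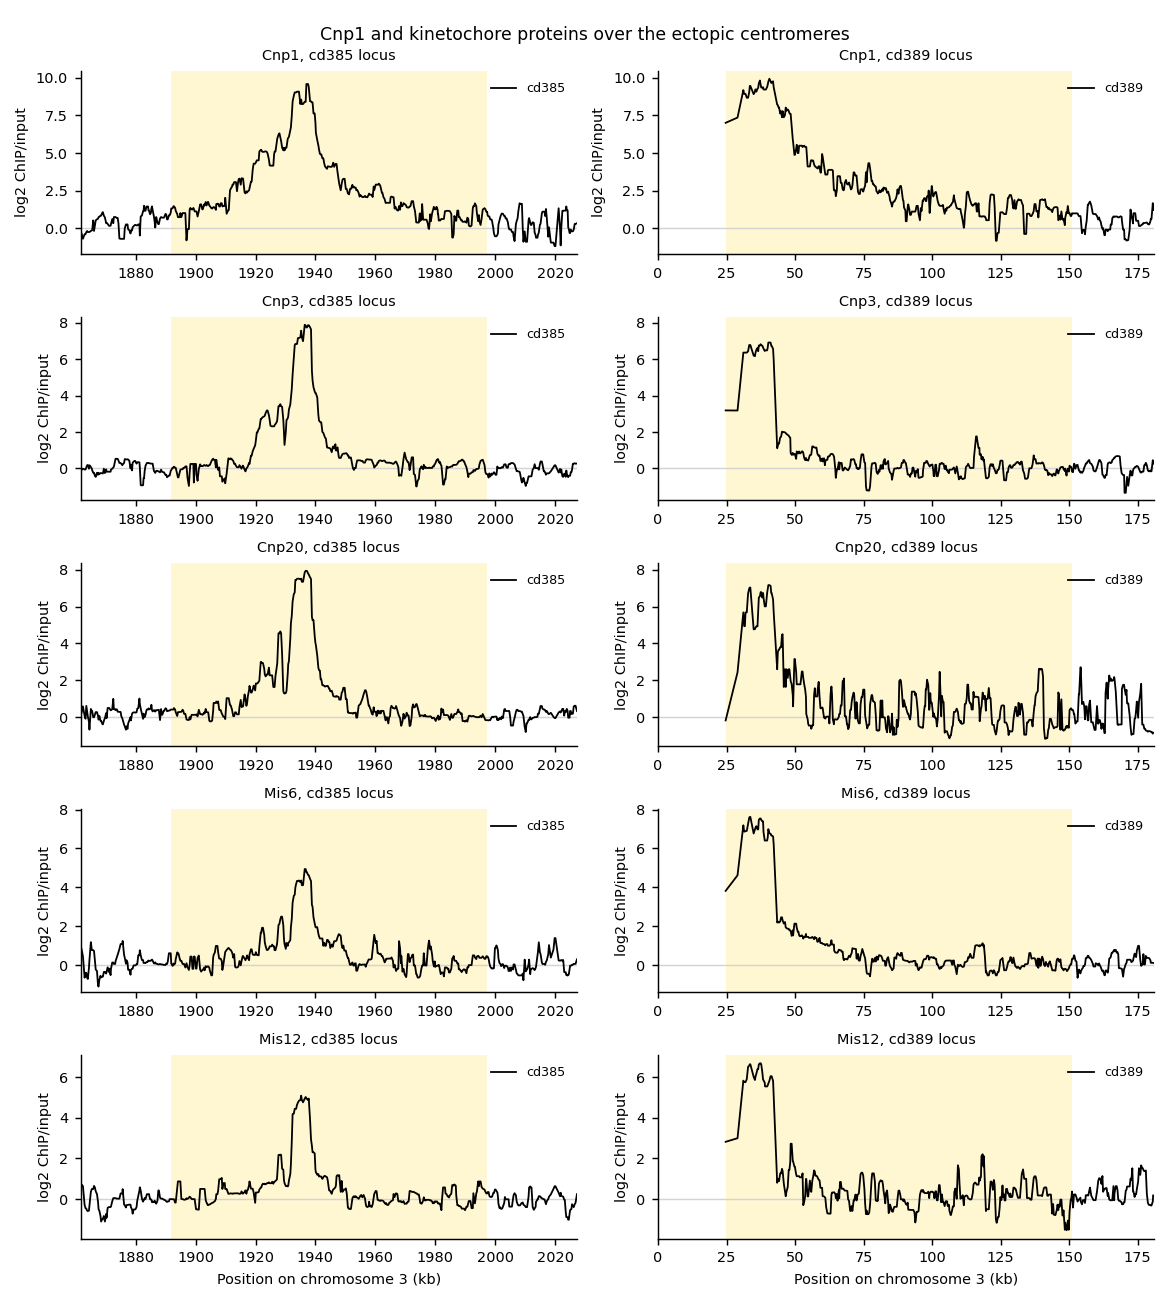
Running median over 2 kb of the log2 ChIP/input ratio (vertical axis) along chromosome 3 (horizontal axis, position in kb) for Cnp1 and the kinetochore proteins in cd385 and cd389, with the gold band marking the survivor's Cnp1 block. Cnp1 reaches the highest values, with a peak running median of 9.59 in cd385 and 9.94 in cd389. The other proteins peak inside the same band over a shorter stretch.

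In the cd385-r1 derivative the parental ectopic centromere carried no Cnp1 block, whereas cd389-r1 kept one at the parental place. Cnp1 over the cd385 block read -0.09 in cd385-r1 and 2.62 in cd385, a mean difference of -2.69 ± 2.43 (-4.86 over the core). SPCC74.04 differed by -8.38 (0.63 against 9.01), ssp2 by -5.91 (-0.11 against 5.80), mug24 by -5.29, ppn1 by -4.83 and the non-coding RNA gene SPNCRNA.1243 by -9.60. The longest domain that met the rule anywhere outside the native centromeres on chromosome 3 of cd385-r1 was 9.08 kb at a mean of 0.84, from 862318 to 871395. In cd389-r1 the block ran from 24619 to 134343 (109.7 kb, 2.51 ± 2.38), with SPCC1884.01 at 8.74, nic1 at 6.34, SPCC757.02C at 6.16 and hsp3101 at 5.51. Over the cd389 block it was lower than in cd389 by a mean difference of -0.56 ± 1.30 (2.26 against 2.72).

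Lower Cnp1 was not limited to the ectopic centromere in cd389-r1: the native cores of centromeres 1 and 2 differed by -1.49 and -1.74, and after each array was scaled to its own native centromeres 1 and 2 the block differed by -0.14. With a common input the same difference was -1.87. The block of cd385 stood at percentile 0.32 of random runs for the difference between cd385-r1 and cd385, and that of cd389 at percentile 0 for the difference between cd389-r1 and cd389. Both blocks were chosen for high Cnp1 on the survivor's array, which is subtracted here. Low percentiles therefore follow in part from that choice and are not a test of the difference. In cd386-r2, which has no parental array here, the native cores read 7.51 and 7.88, and the longest stretch that met the rule on chromosome 3 was 17.5 kb at a mean of 0.38 among 137 domains called across the genome, so no ectopic block stood out.

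Away from the loci, both r1 contrasts held many genes that differed by at least 1: 727 higher and 810 lower in cd385-r1, and 625 higher and 554 lower in cd389-r1, of 7609 measured. Among the genes lower at every probe, 38 lay in the cd385 block for cd385-r1 and 12 in the cd389 block for cd389-r1. The genes higher in cd385-r1 included the translation factor genes tif51 (3.41) and tef101 (2.85), rpl401 (2.75), cox5 (2.92), the desaturase gene ole1 (2.74) and knh2 (3.08). Of the fixed lists, 18 of 35 ribosomal protein genes were higher by at least 1 in cd385-r1 (list median difference 1.1, from -0.42 to 0.78), 4 of 7 histone genes (1.25) and 6 of 11 glycolysis and housekeeping genes (1.42), but with a common input these 3 medians were 0.17, 0.42 and -0.28. The random lists of genes matched on their cd385 value gave percentiles of 100, 99.56 and 100. Cnp1 in the vector and dh2.1 lines of cd385 was also above cd385 for these lists, so the differences were not particular to cd385-r1. Their medians were 0.49 and 0.66 for the ribosomal list, 0.53 and 0.50 for the histone list and 1.04 and 1.62 for the glycolysis list. In cd389-r1 the ribosomal list went the other way (-0.29, with 10 of 35 lower by at least 1), the histone list read 0.60 (percentile 90.6, 5 of 7 genes higher and 2 lower, 0.20 with normexp) and the glycolysis list read -0.16, with a sign that changed with the scaling. Single genes such as tim15 (3.37), the histone gene htb1 (2.37) and ecm33 (2.28) were higher while deb1 (-3.07), the pheromone receptor gene mam2 (-2.96) and lsd90 (-2.86) were lower. Subtelomeric genes (medians 0.03 and -0.12) and island genes (0.03 and 0.13) differed little, and their signs changed with the scaling, as did that of the stress list in cd389-r1 (0.02; 0.66 in cd385-r1). None of the mating type genes had 3 single-match probes.

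**Figure D2:**
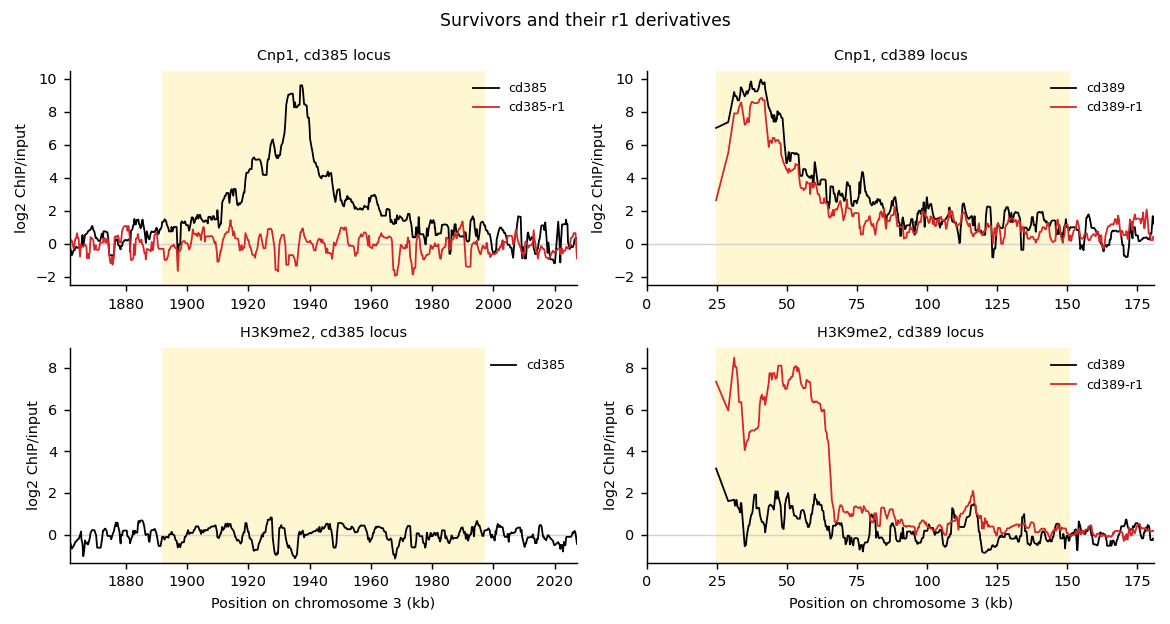
Running median over 2 kb of the log2 ChIP/input ratio (vertical axis) along chromosome 3 (horizontal axis, position in kb) for Cnp1 and H3K9me2 in the survivors (black) and their r1 derivatives (red), with the gold band marking the survivor's Cnp1 block. Cnp1 averages -0.09 over the cd385 block in cd385-r1, and H3K9me2 averages 2.17 over the cd389 block in cd389-r1; the cd385 panel of H3K9me2 holds the survivor alone.

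H3K9me2, the histone mark of heterochromatin, was near the array's median over the cd385 centromere and low over that of cd389, and was far higher in cd389-r1. The mean over the block was -0.02 ± 0.60 in cd385, where no domain met the rule. It was 0.35 ± 0.92 in cd389 (0.80 over the core, with a domain of 38.3 kb at a mean of 1.17). In cd389-r1 it was 2.17 ± 2.75 over the same cd389 block (4.88 over the core, with a domain of 63.1 kb at a mean of 4.15 from 24619 to 87752). The descriptions of the cd389-r1 and cd389-vector samples name the mark H2me2K9, whereas their titles and antibody fields name H3K9me2, as which both are treated here. Genes of the block differed the most between cd389-r1 and cd389: hsp3101 read 7.98 against 0.92, ctt1 7.24 against 0.37, SPCC757.05C 7.80 against 0.93 and SPCC757.04 7.52 against 1.56. Of the 55 genes higher at every probe by a mean of at least 1, 28 lay in the block. The mean difference over the block was 1.88 ± 2.35 (4.19 over the core, percentile 99.99), and the mean for cd389-r1 was 0.79 when the median over probes was used and 3.92 over the narrower block of threshold 1.5.

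At subtelomeric genes, facultative islands, the region around mat3 and the native centromere cores, cd389-r1 read lower than cd389. The subtelomeric genes had a list median of 0.91 against 1.67 (difference -0.73, with 15 of 55 lower by at least 1), among them the lactate dehydrogenase gene SPAC186.08C (-2.28) and say1 (-2.16), although the median difference turned to 0.22 when the arrays were scaled to 1 median absolute deviation. The facultative islands, meiotic genes silenced by heterochromatin during growth, had medians of 5.26 against 6.31. Their difference was -0.93, with 3 of 7 lower by at least 1, and the same scaling turned it to 4.72. The region around mat3 differed by -1.0 and the native cores of centromeres 1 and 2, where Cnp1 lies, by -1.34 and -1.93. The repeats beside these cores read 8.39 and 7.87 in cd389-r1, and no difference from cd389 is given for them here. But1 (-2.19), jnm1 (-2.15) and SPBC1683.02 (-2.45) were lower as well, and in all 70 genes were higher and 210 lower by at least 1. Ribosomal (0.33), glycolysis (0.50), stress (0.35) and histone (0.27) lists were slightly higher, with the first 3 of these medians below 0 under a common input. On all 7 H3K9me2 arrays the islands stood at percentile 100 of random gene lists, with medians from 3.22 in cd385 to 6.31 in cd389, mei4 from 4.67 to 7.48, ssm4 from 3.72 to 7.10 and mcp7 from 3.87 to 6.92.

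Scm3 was higher in cd389-r1 than in cd389 over the ectopic core and at the native centromeres alike. SPCC1884.01 read 6.38 against 4.48, the non-coding RNA gene SPNCRNA.1097 6.15 against 3.81 and the reductase gene SPCC330.03C 1.09 against -0.63. The mean over the block differed by 0.18 ± 1.12 (0.54 over the core, percentile 99.96), within a range of -0.11 to 0.54 over the settings tried, and the native cores differed by 1.20 and 1.12. The gene acp2 (-2.13) and the mitochondrial gene atg44 (-1.88) were lower, and 91 genes were higher and 222 lower by at least 1. The glycolysis list had a median difference of 0.40, the subtelomeric list 0.17, the stress list 0.21 (0.02, 0.12 and 0.06 under the settings that gave the lowest values), and the histone (0.28), island (0.15) and ribosomal (-0.05) medians changed sign with the scaling.

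Integration of dh2.1, whose control is the integrated vector in the same survivor, went with H3K9me2 and Swi6 over the ectopic centromere in both survivors. H3K9me2 over the cd385 block read 2.41 in cd385-dh2.1 and -0.06 in cd385-vector (difference 2.48 ± 2.32, 5.18 over the core, where 100% of probes were higher), and over the cd389 block 1.67 against 0.10 (1.57 ± 2.57, 3.76 over the core). The sensor kinase gene mak3 read 7.83 against 0.05, ppn1 5.83 against 0.04, sly1 5.88 against 0.33, SPCC74.04 4.83 against -0.08 and the vacuolar transporter gene hmt1 4.38 against -0.13 in the cd385 lines. In the cd389 lines hsp3101 read 9.21 against 0.17, nic1 8.68 against 0.71, SPCC757.02C 8.64 against 0.68 and SPCC757.04 6.14 against 0.15. Domains of 65.0 kb (1907847 to 1972875, mean 3.77) and 40.3 kb (24619 to 64875, mean 5.29) were called at the 2 loci with dh2.1 and none with the vector. Swi6 followed with smaller values, at 0.94 ± 1.27 over the cd385 block (2.05 over the core) and 0.74 ± 1.19 over the cd389 block (1.49 over the core), with mak3 higher by 4.28, hsp3101 by 4.37, SPCC757.02C by 4.19 and nic1 by 3.84. The native cores of centromeres 1 and 2 were also higher in Swi6 with dh2.1, by 1.14 and 0.83 in the cd385 lines and 0.64 and 0.97 in the cd389 lines.

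For Cnp1 the difference between dh2.1 and vector lines was 0.06 ± 0.83 over the cd385 block and 0.19 ± 0.95 over the cd389 block (0.31 and 0.15 over the cores). Random runs on the arms of chromosome 3 differed by 0.17 and 0.53, so in the cd389 lines the block was higher by less than the arms were. In the cd389 lines nic1 (6.52 against 4.35) and SPCC757.02C (6.22 against 4.07) were higher. Scaling each array to its native centromeres gave 0.40 in the cd385 lines, and across settings the value in the cd389 lines ran from -0.11 to 0.48. The blocks stood at percentiles of 99.88 and 100 of random runs for H3K9me2, 99.82 and 99.99 for Swi6, and 11.9 and 1.2 for Cnp1 (cd385 lines, then cd389 lines). With 1 array of each line and no replicate integrants, the spread between independent integrations is not known.

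Outside the loci, aur1, the inositol phosphorylceramide synthase gene, was higher in H3K9me2 by 5.90 and 7.30 and in Swi6 by 2.77 and 2.98 (cd385 lines, then cd389 lines), with a signal that ended at the gene. SPCC569.03 (8.06) and SPCC569.05C (7.92) at the right end of chromosome 3 were also higher in cd389-dh2.1; that end holds probes similar in sequence to the left-end block. In the cd385 lines 249 genes were higher and 28 lower in H3K9me2 by at least 1, and of those higher at every probe 30 of 164 lay in the block. In the cd389 lines the numbers were 51 and 53, with 22 of 48 in the block. Of those lower at every probe, 10 of 14 and 13 of 48 were subtelomeric. The lower genes included pho84, a phosphate transporter gene (-1.44 and -1.66), and nrg1 (-1.23) and fub2 (-1.22) in the cd385 lines. In the cd389 lines gal1 (-1.64) was among them, and but1 (-1.77) and cup1 (-1.65) were lower too. The median over the subtelomeric genes (54 and 55 measured) was close to 0 (-0.09 and 0.06) and changed sign with the scaling. Ura4 differed by -2.15 in the cd389 lines, but its input was nearly absent on these arrays and the value is not interpretable. For Swi6, 139 genes were higher and 17 lower in the cd385 lines and 124 and 21 in the cd389 lines, with hsp16 (-1.23) and prs5 (-1.18), then cwf12 (-1.37), ect1 (-1.36) and pep12 (-1.13), among those lower.

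The glycolysis list was higher in Swi6 with dh2.1 in both survivors, with 5 of 11 and 6 of 11 genes higher by at least 1 and median differences of 0.67 and 1.18, each at percentile 100 of matched random lists. This list was already high in Swi6 of the vector lines (medians 0.98 and 0.81) and varied between arrays of other proteins. It read 1.53 for Mis6 and 1.64 for Mis12 in cd389, but -0.03 and -0.26 in cd385. A gain of Swi6 at these genes therefore cannot be told apart from variation between arrays. The ribosomal list read 0.35 and 0.35, with 4 of 35 and 0 of 35 higher by at least 1, and 0.06 and 0.08 under the settings that gave the lowest values. The other lists had median differences between -0.23 and 0.46 in Swi6, and in H3K9me2 the 6 lists lay between -0.43 and 0.52; most of these changed sign under at least 1 scaling of the arrays. For Cnp1 the list medians lay between -0.21 and 0.32, and 215 genes were higher and 185 lower in the cd385 lines, 220 and 96 in the cd389 lines. The region around mat3 was higher in Swi6 by 1.00 and 0.98, but from values below the array's median in the vector lines (-0.67 and -0.99). With dh2.1 it read 0.33 and -0.01, at percentiles of 87.9 and 46.8 of random runs. No enrichment of Swi6 was therefore seen there in cd389-dh2.1.

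**Figure D3:**
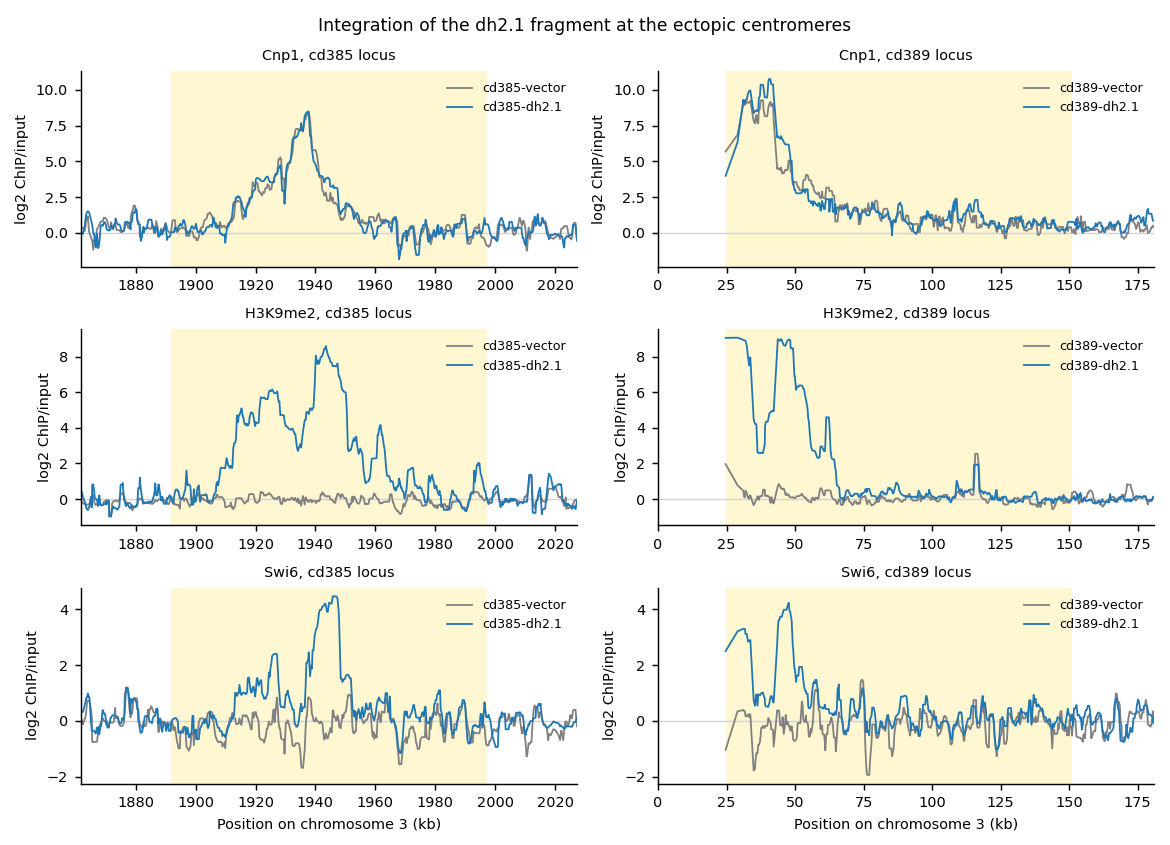
Running median over 2 kb of the log2 ChIP/input ratio (vertical axis) along chromosome 3 (horizontal axis, position in kb) for Cnp1, H3K9me2 and Swi6 in the vector (grey) and dh2.1 (blue) lines of cd385 and cd389, with the gold band marking the survivor's Cnp1 block. H3K9me2 averages 5.18 and 3.76 more over the cores with dh2.1 than with the vector, and Cnp1 0.31 and 0.15 more.

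Pht1, the fission yeast H2A.Z, was lower over each ectopic centromere in the strains that carry it than in the other strains, and part of that difference was shared by the arms of chromosome 3. Over the cd385 block the value was -0.34 in cd385 and -0.02 ± 0.14 (SD over the other 6 arrays), a difference of -0.32. Over the cd389 block cd389 read 0.14 and cd389-r1 0.17 against 0.42 ± 0.20 in the other 5 arrays (-0.26), and over the cd389-r1 block 0.14 and 0.14 against 0.44 ± 0.20 (-0.30). The narrower cores gave larger differences. Over the cd385 core cd385 read -0.60, and the other arrays from -0.44 (cd389) to -0.02 (wild-type). Over the cd389-r1 core cd389-r1 read -0.46 and cd389 0.14, and the other arrays from 0.48 (Dmsc1) to 1.03 (wild-type). The arms of chromosome 3 outside the blocks differed as well, by -0.20 in cd385, -0.18 in cd389 and 0.06 in cd389-r1. Relative to them the differences over the 3 blocks were -0.12, -0.20 and -0.24, of which cd389-r1 made up the larger part: over the cd389 block it read -0.09 and cd389 0.12, against 0.21 ± 0.09 in the other arrays, and cd389 was not below cd39 (0.09). Among random runs on the arms the cd385 block stood at percentile 7.23 in cd385, and from 10.0 (cd389) to 17.0 (wild-type) in the other arrays. The cd389 block stood at 77.2 in cd389 and 33.4 in cd389-r1. In the non-carriers it ran from 71.75 (cd39) to 96.8 (wild-type), so here too cd389 was not below cd39. In cd385 28 of 32 genes of the block were lower than the mean of the other arrays, with a median difference of -0.26, and 13 were below every other array. Only 20 of the 32 differed by more than the arms did. The genes ssp2 (-0.51), the midasin gene mdn1 (-0.48), pof6 (-0.45), sly1 (-0.44) and mak3 (-0.44) were the furthest apart along with SPCC737.04 (-0.47). In cd389 39 of 43 genes were lower than the mean of the 5 non-carriers (median difference -0.19). Of these genes 9 were below each of those 5 arrays, and a share expected by chance was not worked out. The lowest were chiefly SPCC1884.01 (-1.17, at -0.36 against 0.81), then pmp20 (-0.45) and aah1 (-0.41). Of the 43 genes 23 lay below the difference of the arms.

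In the derivative cd389-r1 17 of the same 43 genes were lower and the median difference was 0.08. Relative to the arms 21 were lower, close to the 23 of cd389, while a few genes of the core were far lower: hsp3101 by -2.38 (-0.73 against 1.65 ± 0.33), SPCC1884.01 by -1.89, nic1 by -1.43, SPCC757.02C by -1.18, SPCC757.05C by -0.90 and SPCC757.04 by -0.70. Averaged over the 3 blocks, carriers differed from the other arrays by -0.30, the lowest of 105 assignments of carriers to the 7 arrays (exact permutation test, one-sided, p = 0.00952, the smallest the design allows). Since cd389-r1 derives from cd389 and their blocks overlap, these are not 3 independent loci. Arrays of the same slide gave the same direction, with differences from -0.27 to -0.37 for the 5 pairings of a block with a carrier. Without a centromere there, cd389 read -0.25 over the cd385 block and cd385 0.24 over the cd389 block, both nearer to the carriers than to wild-type (0.11 and 0.64). Against only the arrays with the most similar gene profile, cd385 differed by -0.09 and cd389 by -0.10, and cd389-r1 by -0.46. With a common input in place of each array's own the mean was -0.26 and p was 0.0667, or 0.0762 with a common input of the Pht1 arrays, so in these settings the permutation test no longer passed 0.05. Relative to the arms of chromosome 3, a baseline chosen after the data were seen, the mean was -0.19 (exact permutation test, one-sided, p = 0.0190).

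**Figure D4:**
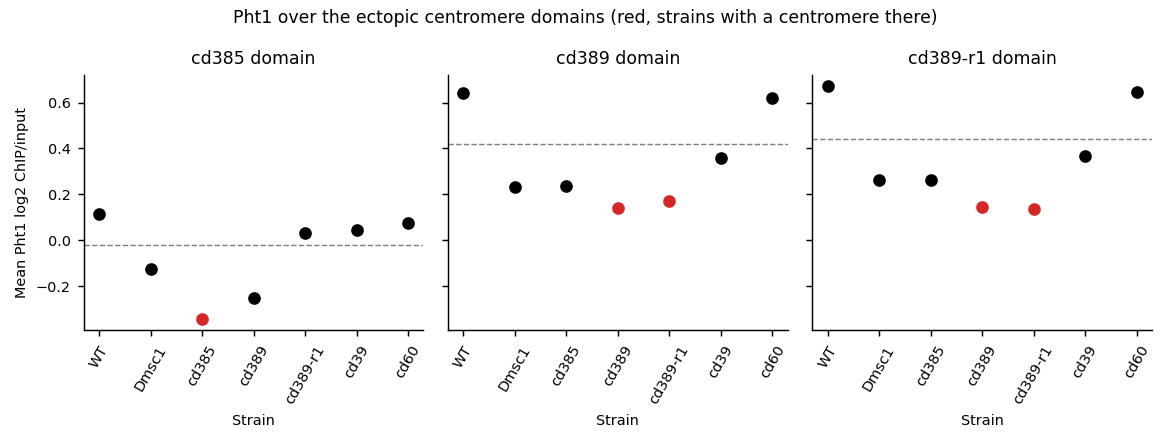
Mean log2 Pht1 ChIP/input ratio (vertical axis) over each ectopic Cnp1 block on the 7 Pht1 arrays, 1 panel per block and 1 point per strain (horizontal axis), with strains that carry the centromere there in red and the mean of the others as a dashed line. The carriers have means of -0.34, 0.15 and 0.14 at the cd385, cd389 and cd389-r1 blocks and the other arrays -0.02, 0.42 and 0.44.

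Pht1 was low at the native centromeres and subtelomeres of all strains but Dmsc1. The cores of centromeres 1 and 2 averaged -1.19 ± 0.09 and -1.44 ± 0.07 over the strains other than Dmsc1 that keep them (-0.95 ± 0.55 and -1.25 ± 0.51 with Dmsc1), and the 4 subtelomeres of chromosomes 1 and 2 -0.78 ± 0.09 over the 6 other strains (SD over strains). In Dmsc1, where the gene for the JmjC-domain protein Msc1 is deleted, the subtelomeres were higher by 0.70 than in the other 6 strains. Against wild-type the core of centromere 1 read 0.02 against -1.08, its repeats -0.14 against -1.53, the core of centromere 2 -0.11 against -1.38, its repeats 0.02 against -1.25, and the region around mat3 0.09 against -0.57. The outermost 100 kb of chromosomes 1 and 2 read -0.11 or 0.01 in Dmsc1 and -0.78 to -0.68 in wild-type. Among the neocentric strains the right end of chromosome 2 read -1.21 in cd389 and the right end of chromosome 1 -0.19 in cd60. With a common input the core of centromere 1 was 0.13 on average, and that of centromere 2 -0.13.

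Gene by gene the Dmsc1 profile was flatter than that of wild-type. By at least 1, 107 genes were higher and 854 lower in Dmsc1, against a median difference of -0.31 over all 7609 genes; the lower genes had a median of 1.59 in wild-type and 0.26 in Dmsc1, and the higher genes -0.87 and 0.31. Of the 55 subtelomeric genes 17 were higher by at least 1, and the list's median difference was 0.71 (-0.51 in wild-type, 0.31 in Dmsc1, percentile 100 of matched random lists); the largest differences were at SPAC186.08C (2.09), SPAC186.07C (1.81), SPAC212.07C (1.67) and SPBPB8B6.02C (1.64). Glycolysis genes had a median difference of 0.76, with 3 of 11 higher by at least 1, namely adh1 (1.38), fba1 (1.22) and eno101 (1.09), and ribosomal protein genes one of 0.44, from -0.91 in wild-type. The histone list read 0.27, with hht2 higher by 1.1, and turned to -0.02 with the arrays scaled to 1 median absolute deviation. Higher values of these 3 lists were not particular to Dmsc1. In cd39 the glycolysis, ribosomal and histone medians were 0.58, 0.07 and -0.03, above those of Dmsc1 (0.24, -0.37 and -0.58). The islands read -0.21, with num1 at -0.80 and spo5 at -0.82, closer to 0 than the median over all genes, and the stress list 0.03, with sro1 at -0.78 and hsp16 at -0.74 and a sign that changed with the scaling. Hnt1, with 2.67 in wild-type and -0.01 in Dmsc1, was the lowest protein-coding gene of the contrast. The SD over genes of the difference was 0.58, against 0.14 to 0.49 in the 15 pairs of Pht1 arrays without Dmsc1 and 0.49 to 0.56 in the 5 other pairs with it. Depending on the settings, 38 to 256 genes were higher and 295 to 1568 lower.

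**Figure D5:**
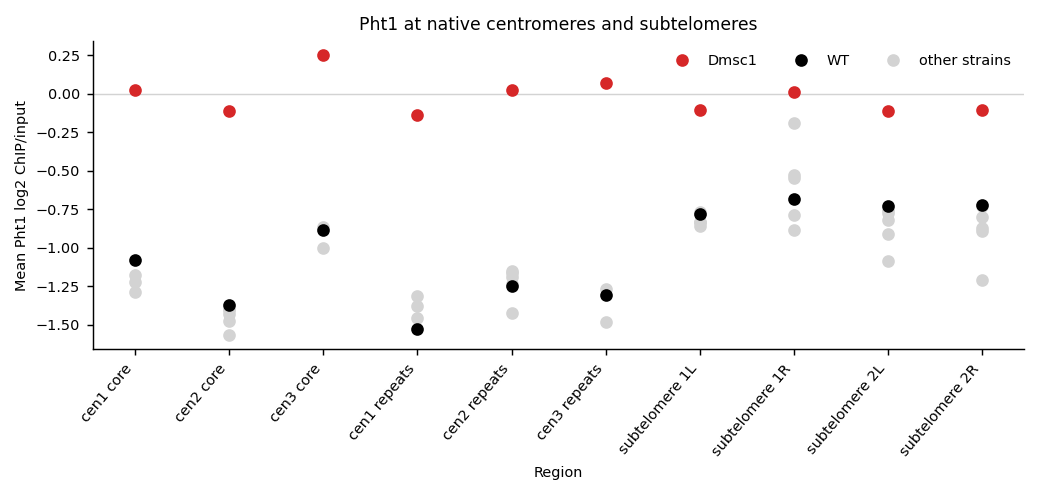
Mean log2 Pht1 ChIP/input ratio (vertical axis) on the 7 Pht1 arrays at native centromeres and subtelomeres (horizontal axis), 1 point per array, with a strain left out at its own deleted centromere. Dmsc1 lies between -0.14 and 0.25 at the centromeres, where wild-type lies between -1.53 and -0.88.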

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

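All tests in this part were chosen only after the result was seen, except the test of the islands, whose prediction was written before its value was known.

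The input DNA itself was lower over an ectopic centromere on some arrays of the strain that carries it than on the lowest of 4 Pht1 arrays of strains with no centromere at either place (wild-type, Dmsc1, cd39 and cd60). Only the arrays below that lowest value are listed here. Over the cd385 core the input in cd385 read -1.16 on the Cnp1 array, -0.93 for Cnp3, -0.69 for Cnp20, -0.96 for Mis6, -0.68 for Mis12 and -0.104 for H3K9me2 (log2, relative to the array's median), and on the 4 control arrays it averaged -0.05. The lowest control read -0.098, so H3K9me2 passed only barely. Over the cd389 core the input in cd389 read -0.74 on the Cnp1 array, -0.65 for Cnp20 and -0.85 for Mis6, and the control arrays averaged -0.21, with the lowest at -0.57. The other arrays of cd389 did not pass, among them Cnp3, Mis12 and Scm3, whose ChIP over that core read 1.75, 1.76 and 1.02.

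Lower copy number of the locus and poorer entry of its chromatin into the input of these strains are argued against, because on the Pht1 and H3K9me2 arrays of the same 2 strains the input over the own core differed from the control arrays by 0.025 (SD of the control arrays 0.14). Processing by the image software is argued against as the only source, since the raw input on the Cnp1 arrays was also lower, by -0.78 (-0.82 after processing). Competition between the channels where ChIP DNA is abundant may account for the pattern: at the 7 measured islands the input on the H3K9me2 arrays minus that on the Cnp1 arrays averaged -0.74 ± 0.59 (SD over islands). It was lower at 6 of 7, with mei4 at -1.72 and spo5, whose mean H3K9me2 was -0.04, at 0.15. A difference between single chromatin preparations was not tested.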

How the results depend on the processing

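The common inputs, the block at a threshold of 3 and 4 further comparators for Pht1 were chosen only after the data were seen; all other settings, like the comparisons and gene lists, were fixed before the data were examined. Of 401 alternative values over 25 settings, 304 stayed by a fixed rule, 94 moved, 2 lost the test's threshold and 1 reversed. By that rule a value could shift by its spread at most, and by no more than the larger of 0.3 and 0.5 times its size. Near 0 this leaves the sign free, and a value inside its spread can still count as moved. Counts, lengths and Pht1 comparisons without a p had to stay within a ratio of 1.5, and the permutation test on its side of 0.05. Where a value moved, the cause was not tested unless it is named. A filter on dim probes (38 values), a domain threshold of 0.7, windows of 1 and 4 kb and scaling by the pericentromeric repeats moved none of the values they were run on. Pht1 at the ectopic centromeres kept its direction under all 18 alternatives. It ran from -0.64 over the cores at a threshold of 3 to -0.19 relative to the arms of chromosome 3 (p = 0.0190, permutation). Against wild-type alone it was -0.49. With a common input of the Pht1 arrays it was -0.26 (p = 0.0762, permutation), and with that of all arrays -0.26 (p = 0.0667, permutation). The sign varied across settings for 3 values near 0: Cnp1 in the cd389 dh2.1 and vector lines (-0.11 to 0.48), Scm3 in cd389-r1 and cd389 (-0.11 to 0.54) and H3K9me2 over the cd385 block (-0.05 to 0.16).

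With normexp the cd389-r1 block was 66.7 kb, Cnp1 at centromere 3 4.34, Scm3 in cd389-r1 1.08, Pht1 at the subtelomeres of the 6 other strains -0.66 and the count of genes higher in Dmsc1 256. With loess Cnp1 at centromere 3 was 3.50, Pht1 at the centromere 2 core -0.67 and at the subtelomeres -0.50, Dmsc1 minus the others 0.52 and the count lower in Dmsc1 315. The authors' log2 table gave Cnp1 at centromere 3 2.95, Cnp3 in cd389 0.99, Cnp1 in cd389-r1 minus cd389 -0.21, Pht1 at the centromere 2 core -0.64 and at the subtelomeres -0.49, Dmsc1 minus the others 0.51 and 299 genes lower. Without centring, Cnp1 at centromere 3 was 4.62 and Pht1 at the subtelomeres -0.68. Centring on the arms gave -0.61 at the subtelomeres, Dmsc1 minus the others 0.60, 38 genes higher and 1568 lower; by construction it shifts every gene by 1 constant per array. Scaling to 1 median absolute deviation gave 63 genes higher and 298 lower.

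A threshold of 1.5 gave blocks of 66.7 kb in cd389 and 64.3 kb in cd389-r1, and a gap of 1 kb blocks of 24.9 (cd163), 45.3 (cd166), 62.4 (cd385), 51.4 (cd389) and 32.7 kb (cd389-r1), by construction of the narrower rule. With the median over probes the values over the blocks were lower: Cnp3 0.39 in cd385 and 0.25 in cd389, Cnp20 in cd385 0.54, Mis6 in cd389 0.42, Mis12 in cd389 0.36, Scm3 in cd389-r1 0.32, H3K9me2 0.45 for dh2.1 minus vector in the cd389 lines and 0.79 in cd389-r1. It also gave Pht1 -0.90 at the subtelomeres, Dmsc1 minus the others 0.93 and 179 genes higher.

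Narrower blocks moved many means away from 0. At a threshold of 1.5 Cnp3 was 1.34 in cd385 and 1.31 in cd389, and in cd389 Cnp20 was 1.78, Mis6 1.97, Mis12 1.41 and Scm3 0.76. Scm3 in cd389-r1 was 1.23, Cnp1 in cd389-r1 minus cd389 -0.97, H3K9me2 and Swi6 for dh2.1 minus vector in the cd389 lines 2.99 and 1.25, and H3K9me2 in cd389-r1 3.92. At a threshold of 3 (cd385, then cd389) Cnp3 was 2.56 and 1.75, Cnp20 2.96 and 2.20, Mis6 1.68 and 2.48, Mis12 1.48 and 1.76, Cnp1 in r1 minus survivor -4.86 and -1.09, H3K9me2 for dh2.1 minus vector 5.18 and 3.76 and Swi6 2.05 and 1.49. Scm3 was 1.02 in cd389 and 2.44 in cd389-r1, their difference 0.54, and H3K9me2 0.80 in cd389 and 4.88 in cd389-r1. Scaling by native centromeres 1 and 2 gave Cnp1 -0.14 for cd389-r1 minus cd389 and 0.40 for cd385-dh2.1 minus cd385-vector.

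With the common input the blocks were 65.1 kb in cd389 and 66.1 kb in cd389-r1, Cnp1 at centromere 3 was 6.95, Cnp3 in cd389 1.24, Mis6 0.16 in cd385 and 1.61 in cd389, Mis12 0.22 and 1.18, Scm3 0.85 in cd389 and 1.12 in cd389-r1, and Cnp1 in cd389-r1 minus cd389 -1.87. Pht1 at the centromere 1 core reversed to 0.13 and at the centromere 2 core was -0.13, with -0.51 at the subtelomeres, Dmsc1 minus the others 0.81, 62 genes higher and 295 lower. For the cores part of the cause lies in the construction, because the common input includes arrays on which strong ChIP signal goes with low input there. The common input of the Pht1 arrays gave 46 genes higher and 407 lower in Dmsc1. Signal over background limits the Cnp1 array of cd389 the most, at 6.64 for ChIP; ratios of dim probes there are the least precise, and with 1 array per group no setting gives an error between arrays.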

Other observations

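The tests of the right end of chromosome 3, of a failed Dmsc1 array, of aur1 and of Pht1 against H3K9me2 were chosen only after the result was seen, as were the genes named in the next 2 paragraphs from within the cores; the test of matched genes in Dmsc1 was set down before its value was known.

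Within the ectopic cores, Cnp1 and heterochromatin were both present in the dh2.1 lines but peaked at different genes. In cd385-dh2.1 SPCC74.04 had the highest Cnp1 (7.91) with H3K9me2 at 4.83 and Swi6 at 1.76, whereas mak3, within 10 kb of it, had Cnp1 at 3.57, H3K9me2 at 7.83 and Swi6 at 4.21. In cd389-dh2.1 SPCC1884.01 read 10.25 for Cnp1, 3.59 for H3K9me2 and 1.24 for Swi6, and hsp3101 5.77, 9.21 and 4.33. The derivative cd389-r1, whose labels name no dh2.1, had the same order: 8.74 and 5.18 for Cnp1 and H3K9me2 at SPCC1884.01, 5.51 and 7.98 at hsp3101, and 3.33 and 7.24 at ctt1.

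The survivors also differed in heterochromatin away from their centromeres. H3K9me2 over the repeats of centromere 1 was 6.35 in cd385 and from 8.39 to 9.21 on the 6 other arrays, and the islands were lowest in cd385 as well (median 3.22, against 4.39 to 6.31). With 1 array of cd385, a weaker immunoprecipitation and less heterochromatin were not told apart. Over the right end of chromosome 1 cd385 and its derivatives read 2.56, 3.98 (vector) and 3.30 (dh2.1), and cd389 and its derivatives 2.20, 1.5 (vector), 1.88 (dh2.1) and 1.45 (r1). Of the islands, rec8 reached 1.67 in cd389 and spo5 at most 0.48, while num1 ran from 3.22 to 6.31 and mug8 from 2.50 to 4.65. In Pht1 the right end of chromosome 1 read -0.19 in cd60 and -0.89 in cd39, the other strain that lost centromere 1.

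In cd389, Cnp1 signal also appeared at the right end of chromosome 3, far from the left-end block. Cross-hybridization from similar sequence may account for it: the 11 probes there with sequence similar to the left-end block (median identity 94.9%, from 2427961 to 2433123) averaged 7.71 ± 2.22 and the 230 others -0.59 ± 1.26, a difference of 8.30, and 3 of the 230 reached 2. Similarity alone was not enough elsewhere: similar probes at the ends of chromosome 2 in cd389 averaged -0.04 and 1.11 (2 each, 89.6% and 87.5% identity), and 3 at the right end of chromosome 1 in cd163 0.89 ± 1.45 (95% identity). A second small Cnp1 domain on the stretch of similar probes was not tested and stays open, and the design offers no test of a biological explanation.

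The flattened Pht1 profile of Dmsc1 has a technical side that was tested in 2 ways. A mislabelled or failed array is argued against, since the input of msc1 was lower than on the other arrays by -9.27 and the profile correlated with wild-type at r = 0.83 over 7215 arm genes, although this was below the lowest of the 5 other strains (0.91) and the slope was 0.60. A lower efficiency of the immunoprecipitation as the only cause is argued against, because heterochromatic regions lay above arm genes with the same wild-type value by 0.78 on average (centromere 1 repeats 0.92, centromere 2 repeats 0.78, subtelomeric genes 0.65). The SD was 0.51 and 0.40 over the genes matched to the repeats and 0.41 over the differences of the subtelomeric genes. Such a rise was not particular to heterochromatin. The glycolysis list, which was not part of this test, had medians of -0.61 in wild-type and 0.24 in Dmsc1. The subtelomeric list had -0.51 and 0.31. A role of Msc1 in keeping Pht1 out of heterochromatin stays open, as does a loss of contrast over the arms, and no biological explanation was tested on this 1 array. The Dmsc1 array shared its slide with no other Pht1 array, so effects of strain and slide cannot be told apart.

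H3K9me2 and Swi6 over aur1 in the dh2.1 lines may come from aur1 sequence on the integrated construct, since the signal ended at the gene: H3K9me2 over 34 probes within 5 kb outside it averaged 0.35 in the 2 dh2.1 lines, and 5.72 and 7.35 over the 8 probes of the gene. Cnp1 over aur1 was also above the flanks in the lines with the vector (1.23 and 1.90) and with dh2.1 (1.53 and 3.02). The labels do not say where either construct was integrated.

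A hypothesis on cd389-r1 is that Pht1 is lower where H3K9me2 was gained. The 10 genes of its block with H3K9me2 of at least 3 had a Pht1 difference from other strains of -0.91 ± 0.81, and the 25 other genes 0.06 ± 0.16, so the split differed by -0.97. In cd389, where the same genes have little H3K9me2, the split gave -0.19. Since 8 of the 10 genes also carry Cnp1 of at least 3 (mean -1.11) and the 2 with H3K9me2 alone averaged -0.12, the data may equally reflect Cnp1 and H3K9me2 together, and these genes cannot show which.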
